A study of Mus musculus with 128 samples.

How the data were processed

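The deposited values were the RSEM expected counts of every transcript in 1 file per library. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.18.0.12, inspected with FastQC 0.11.3 and MultiQC 1.2, aligned to the mouse genome GRCm38 with STAR 2.6.1 and quantified with RSEM 1.3.0. Per the labels, total RNA was isolated with a MagMAX mirVana kit and libraries were made after ribosomal RNA depletion. Read length, strandedness, the gene annotation and whether strain-specific genomes were used are not given in the sources used here, nor is the cocaine dose.

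Each file held 137954 transcripts. Expected counts were summed over the transcripts of each gene and rounded, which gave 54532 genes after 92 spike-in RNAs (External RNA Controls Consortium, ERCC) were set aside. Coordinates and biotypes came from GENCODE M21, where 54495 of the gene identifiers were found. The series gives a median depth of 132M reads, whereas the expected counts summed to a median of 36.5M per library.

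Genes entered the tests with at least 0.5 CPM (counts per 1M counts) in at least 8 libraries, which left 21936 genes. Library sizes were scaled by the trimmed mean of M values (TMM). The model had 1 mean for each of the 32 groups of strain, sex and injection and the centred log2 of the choroid plexus value given in the labels. edgeR 4.0.16 quasi-likelihood F tests with bias-adjusted deviances (glmQLFit with legacy set to FALSE, glmQLFTest) were used, and adjusted p values follow Benjamini and Hochberg over all tested genes, with a threshold of 0.05. Averages over strains, sexes or injections gave each group the same weight. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. Values in CPM are given as mean ± SD with n and use TMM-scaled library sizes, except in the checks of tissue, sex and strain labels of single libraries, where plain totals were used.

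Alternatives chosen before the data were examined were DESeq2 1.42.0, limma 3.58.1 with a trend, the older edgeR quasi-likelihood, median-of-ratios size factors, no filter on low counts, 5 surrogate variables from sva 3.50.0, no choroid plexus covariate, libraries with a choroid plexus value over 50 left out, a covariate for cortical markers, a covariate for the style of the mouse tag, each replicate number left out and each strain left out. DESeq2 was not run for the tests over all strains at once. Alternatives added after the data were seen were scaling to the spike-in RNAs, leaving out the 7SL and 7SK RNAs, leaving out the 2 libraries nearest to another strain with and without the cortical covariate, leaving out each WSB/EiJ, C57BL/6J or NOD/ShiLtJ library, leaving out NZO/HlLtJ male sham 3, which had the largest spike-in share, a comparison of WSB/EiJ with the mean of the other 7 strains and a list of endoplasmic reticulum chaperones.

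Gene lists, 33 in all, were written down beforehand. They covered immediate early, glucocorticoid-responsive, circadian and heat shock genes, striatal, cortical, glial, vascular, choroid plexus, ependymal, meningeal and blood cell types, receptor families, cocaine candidates, sex-linked genes, interferon, histone and mitochondrial genes and genes with known strain variants. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether the members of a list change in a shared direction without reference to other genes. Camera asks whether members rank higher or lower than the other genes. List p values were adjusted over the lists. A marker score is the mean log2 CPM of a list with 0.1 added to each CPM.

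Genes were named by a rule set beforehand: past the threshold, mean CPM of at least 1, no clone or predicted name and no pseudogene, then the largest changes in each direction. For the cocaine average the same sign in at least 6 of 8 strains was also asked, but not for sex. Genes named for strain had a mean CPM of at least 5. Where nothing passed, the smallest p values are given. Some items withheld for evaluation are not reported here. Genes outside the rule are said to be so where they appear, except members shown with a list and genes that check tissue, sex or strain.

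Random regroupings were made with limma-trend, 100 for each comparison with the real one included, and used unadjusted counts where the real count was 0. Permutation p values came from 100000 resamples. A simulation drew counts of each gene independently from the fitted means and dispersions, with 200 genes changed by known folds. Transcripts were tested in the same way as genes, 59530 of them passing the filter. The tests used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.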

Results

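RNA of the striatum, the forebrain region that receives dopamine input and shapes the response to cocaine, was sequenced in 128 mice. They belonged to 8 inbred strains with 16 mice each: CAST/EiJ, PWK/PhJ and WSB/EiJ, which derive from wild mice, and the classical laboratory strains C57BL/6J, A/J, NOD/ShiLtJ, 129S1/SvImJ and NZO/HlLtJ. Of the libraries, 62 were labelled female and 66 male, and 64 came from mice injected repeatedly with cocaine and 64 from sham mice injected with saline. Tissue was taken about 24 hours after the last exposure, on day 19. The 32 groups of strain, sex and injection held 3 to 5 mice, 24 of them 4. Counts summed to 23.2M to 90.6M per library (median 36.5M, cocaine 34.9M, sham 37.8M), with 16710 to 17588 genes over 1 CPM. The comparisons ask which genes differ after repeated cocaine on average, in each sex and in each strain, which differ between females and males, which differ among strains, and whether the effects of cocaine or sex depend on strain or on each other.

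The amount of neighbouring tissue varied among dissections. Slc17a7, which encodes the glutamate transporter of cortical excitatory neurons, ranged from 8.04 to 923 CPM (median 355), and Neurod6, a cortical transcription factor, from 0.212 to 40.6. Drd1, the dopamine receptor of direct-pathway medium spiny neurons, ranged from 29.5 to 344 CPM, and Ppp1r1b, which encodes the striatal phosphoprotein DARPP-32, from 106 to 1639. Ttr, the transthyretin gene of the choroid plexus, ranged from 3.45 to 3303 CPM, and the choroid plexus value of the labels from 2.71 to 764 (median 9.90, with 19 libraries over 50).

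Within groups, the cortical excitatory score fell as the medium spiny neuron score rose (r -0.818, Spearman r -0.872, r without the 2 farthest libraries -0.802, permutation p 1e-05, adjusted p 1e-05 in a family of 4 relations). The cholinergic interneuron score moved against the cortical score in the same way (r -0.834, Spearman r -0.870, r without the 2 farthest -0.820, permutation p 1e-05, adjusted p 1e-05). The log2 choroid plexus value followed log2 Ttr (r 0.986, Spearman r 0.961, r without the 2 farthest 0.984, permutation p 1e-05, adjusted p 1e-05) and the choroid plexus marker score (r 0.981, Spearman r 0.952, r without the 2 farthest 0.980, permutation p 1e-05, adjusted p 1e-05). A p of 1e-05 is the smallest that 100000 resamples allow. The cortical score differed by 0.00582 between cocaine and sham (permutation p 0.982) and by -0.250 between females and males (permutation p 0.323). Its means ran from 3.25 ± 1.24 in NZO/HlLtJ and 3.56 ± 1.57 in WSB/EiJ to 4.72 ± 1.11 in 129S1/SvImJ (n 16 each).

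**Figure D1:**
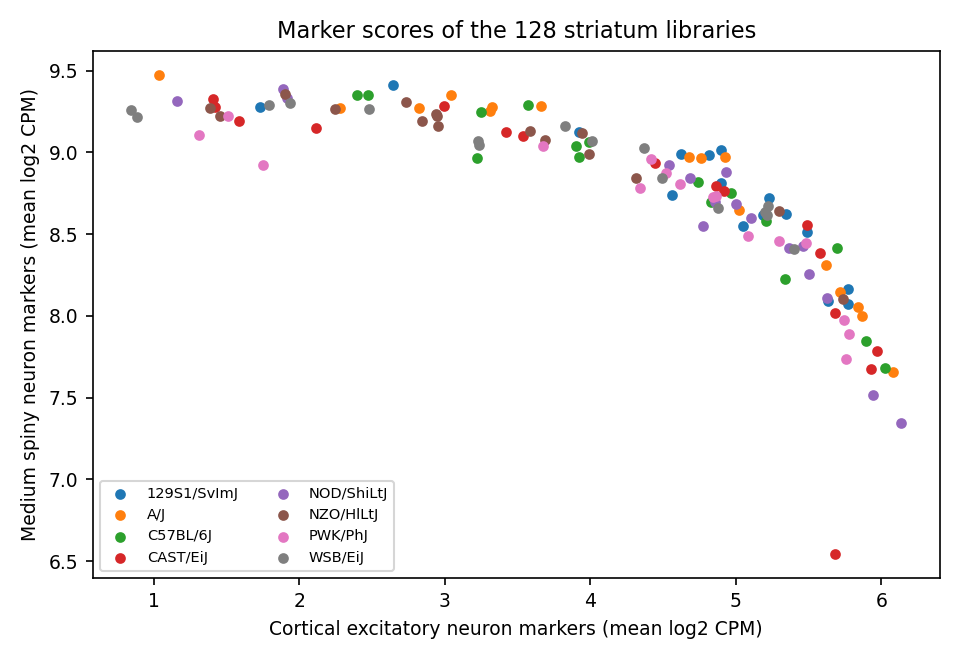
Cortical excitatory score against medium spiny neuron score in 128 libraries; within groups r was -0.818.

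Xist, the RNA that silences 1 X chromosome in females, averaged 1529 ± 309 CPM in 62 females (lowest 862) and 5.69 ± 3.28 in 66 males (highest 17.6). The Y gene Ddx3y averaged 0.0638 and 46.6, but the sex label was itself read from the Y chromosome, so this agreement is no check of it. By the 1000 genes that best separated strains, 126 of 128 libraries lay nearest to the strain of their label. The library labelled A/J female sham 1 lay nearest to C57BL/6J (distance 0.130, against 2.89 to A/J), and the library labelled C57BL/6J female cocaine 3 lay nearest to A/J (0.113, against 2.72 to C57BL/6J). Glo1, the glyoxalase gene that is duplicated in some strains, read 48.5 CPM in the former and 156 in the latter, where the other A/J libraries held 117 to 168 and the other C57BL/6J libraries 37.9 to 55.3. Alad, another gene of variable copy number, read 8.44 and 26.4 CPM (A/J 22.2 to 27.7, C57BL/6J 7.42 to 9.65). Gabra2 read 53.4 and 106 CPM, the latter just below the other A/J libraries (A/J 110 to 148, C57BL/6J 46.2 to 70.3). The tests keep both libraries under their labels.

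**Figure D2:**
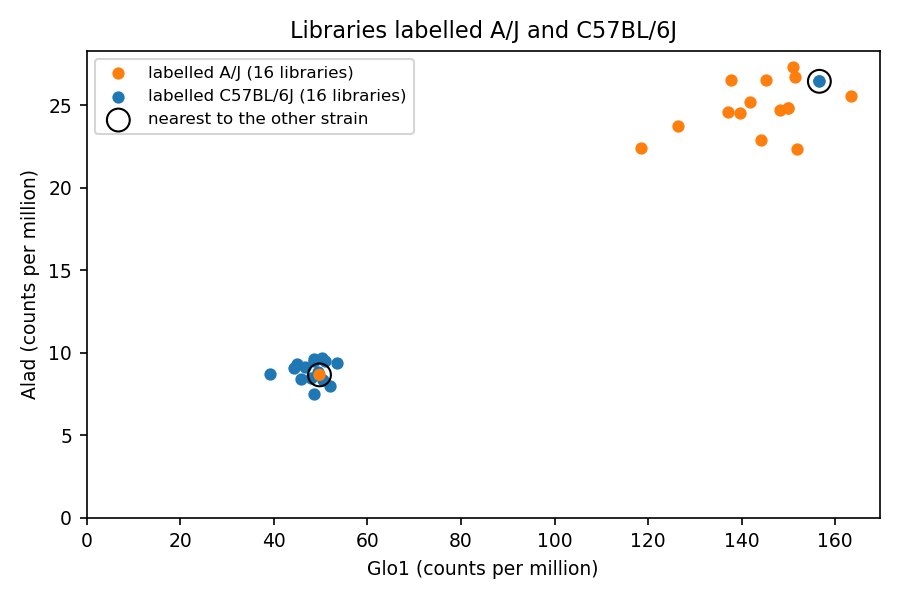
Glo1 against Alad, in TMM-scaled CPM, in the libraries labelled A/J and C57BL/6J (16 each); rings mark the 2 libraries nearest to the other strain.

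Averaged over strains and sexes, no gene separated cocaine from sham mice at 24 hours. Fosb, whose truncated product accumulates in the striatum during repeated cocaine, had a log2 fold change of 0.09 ± 0.07 SE, and Egr2, an activity-induced transcription factor, 0.39 ± 0.16. The stress-related chaperone gene Hspa5 had 0.14 ± 0.05 and Per2, a core clock gene, 0.19 ± 0.08. Fosb, Egr2, Hspa5 and Per2 are shown as members of lists and lie outside the naming rule. None of 21936 genes passed (0 calls in edgeR, with 696 at an unadjusted p under 0.05; DESeq2 called 9, 3 higher and 6 lower, and limma 0). The smallest p belonged to the predicted gene Gm3650, outside the naming rule (0.71 ± 0.16, edgeR adjusted p 0.574). In simulated data with 200 changed genes, the same test recovered 72% of the smallest changes tried and 96% of changes of 1.3-fold, with 7 false calls. The simulated genes varied independently of each other. Real libraries shared differences in dissection, so these figures need not hold for them.

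As lists, immediate early genes, which neurons switch on within minutes of activity, ranked higher after cocaine (24 genes, median log2 0.09, 21 positive, camera adjusted p 0.000399, p = 0.121 with an estimated correlation). Glucocorticoid-responsive genes, whose member Plin4 codes for a lipid droplet protein (0.15 ± 0.07), ranked higher too (16 genes, median 0.05, 13 positive, camera adjusted p 0.00304, p = 0.0617 with an estimated correlation). Circadian genes had 12 of 17 positive (median 0.04, camera adjusted p 0.00272, p = 0.0224 with an estimated correlation, 0.307 after adjustment), and heat shock genes 10 of 13 (median 0.06, camera adjusted p 0.00367, p = 0.0279 with an estimated correlation, 0.307 after adjustment). Endothelial and mural cell markers ranked lower, with 3 of 14 positive (median -0.03, camera adjusted p 0.000399, p = 0.0113 with an estimated correlation, 0.307 after adjustment); their smallest p was that of Pdgfrb, the pericyte growth factor receptor (-0.06 ± 0.03). Myelin genes ranked lower with 1 of 17 positive (median -0.05, camera adjusted p 0.00304, p = 0.316 with an estimated correlation, camera adjusted p 0.0756 without the 2 libraries nearest to another strain); Opalin, a myelin membrane protein, had -0.14 ± 0.06.

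Of the 33 lists, these 6 were called with the preset correlation, 0 with an estimated correlation after adjustment (3 unadjusted) and 0 by fry (1 unadjusted). No member of any list passed over all genes or adjusted over the list alone, where the smallest value was that of Hspa5 (0.0700). The other 27 lists had camera adjusted p from 0.0795 to 0.922, among them ependymal markers at 0.0795, choroid plexus markers 0.0867, direct-pathway markers 0.390, indirect-pathway markers 0.922, dopamine genes 0.830, glutamate receptors 0.622, GABA-A receptors 0.849, opioid genes 0.922 and repeated cocaine candidates 0.762. Cortical markers, the main sign of dissection, had 0.555. Median, mean and camera direction differed in sign in 10 of the lists that were not called: indirect-pathway, GABA interneuron, cortical, dopamine neuron and blood markers, GABA-A receptors, repeated cocaine candidates, interferon genes, Y-linked genes and histone genes.

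In females alone, 0 genes passed in edgeR (1119 at an unadjusted p under 0.05; DESeq2 11, limma 0). In males alone, 0 passed (472 unadjusted; DESeq2 9, limma 0). The difference between the sexes in the response to cocaine was tested directly and also gave 0 genes (895 unadjusted; DESeq2 4, limma 0). Its smallest p values, among genes the naming rule allows, were those of the noncoding RNA Dancr (-0.26 ± 0.07), the vesicle GTPase Rab37 (-1.05 ± 0.28) and the guanine nucleotide exchange factor Plekhg1 (-0.56 ± 0.16), each with an edgeR adjusted p of 1.0.

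Within WSB/EiJ, several genes of the endoplasmic reticulum rose after cocaine. Hspa5 encodes BiP, the main chaperone of that compartment (chromosome 2, 34771970 to 34777547); it measured 228 ± 74.8 CPM in cocaine and 142 ± 17.5 in sham mice (n 8 each), a log2 fold change of 0.73 ± 0.14 (edgeR adjusted p 0.00324). Hyou1, a second chaperone (chromosome 9, 44379490 to 44392369), rose from 115 ± 6.14 to 145 ± 22.0 CPM (0.35 ± 0.06, adjusted p 0.00204). Calr, the calcium-binding calreticulin gene (chromosome 8, 84841850 to 84846934), rose by 0.42 ± 0.08 (adjusted p 0.00324), and Xbp1, the transcription factor of the unfolded protein response (chromosome 11, 5520659 to 5525893), by 0.43 ± 0.10 (adjusted p 0.0319). Sdf2l1 (0.79), Creld2 (0.50), Pdia4 (0.47), Pdia6 (0.44) and Manf (0.40), further genes of protein folding, also rose. Hyou1, Hspa5 and Xbp1 each stood above the highest sham value in 7 of 8 cocaine mice. These genes were chosen after the values were seen, Hyou1 excepted. Hspa5 read 337 CPM in female cocaine 2 and 344 in male cocaine 4, against 156 to 239 in the other WSB/EiJ cocaine mice. Single mice of other strains also read high, such as CAST/EiJ female cocaine 2 (304) and PWK/PhJ male sham 3 (241).

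**Figure D3:**
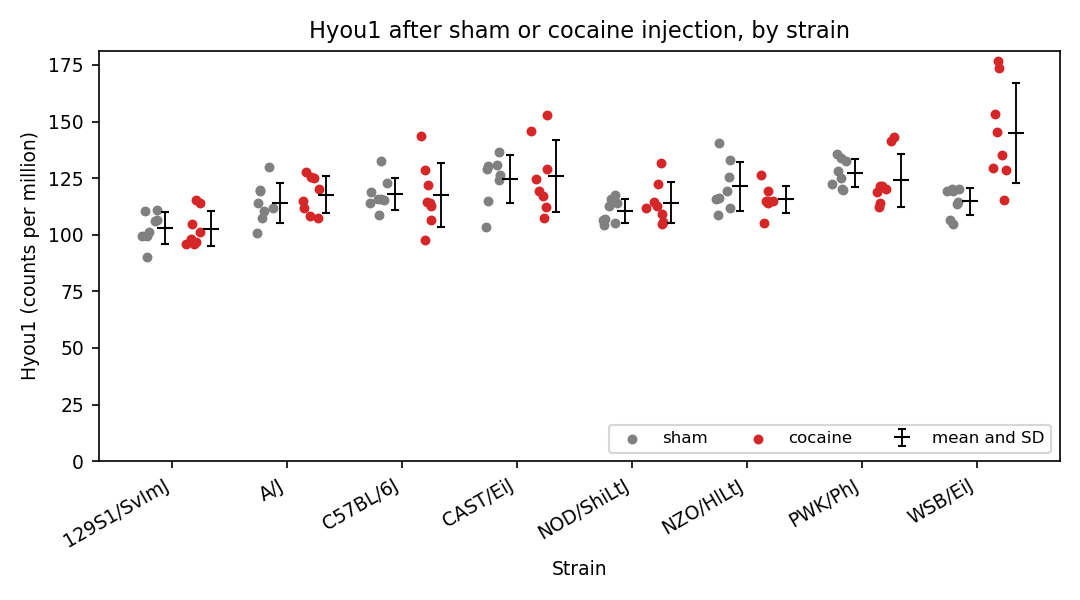
Hyou1 in each library by strain and injection; WSB/EiJ averaged 145 CPM after cocaine and 115 after sham (n 8 each).

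The genes taken by the rule in WSB/EiJ included Fosl2, an activity-induced partner of the AP-1 transcription factor (chromosome 5, 32135801 to 32157842), which rose from 27.8 ± 7.81 to 56.9 ± 28.7 CPM (1.08 ± 0.27, edgeR adjusted p 0.0469). Hspb1, the small heat shock protein 27 gene (chromosome 5, 135887919 to 135889563), rose from 3.29 ± 0.29 to 6.07 ± 2.35 CPM (0.92 ± 0.19, adjusted p 0.00983), and Plekhg4, a guanine nucleotide exchange factor (chromosome 8, 105373274 to 105382862), by 1.03 ± 0.25 (adjusted p 0.0319). Nxpe4, a secreted neurexophilin-like protein gene (chromosome 9, 48162023 to 48400025), had -0.41 ± 0.08 (7.87 ± 0.76 to 6.16 ± 1.01 CPM, adjusted p 0.00983). The centrosomal Lrrcc1 had -0.39 ± 0.08 (adjusted p 0.0129) and the ADP-ribose hydrolase gene Oard1 -0.36 ± 0.08 (adjusted p 0.0319). The WSB/EiJ test called 55 genes, 45 higher and 10 lower (edgeR; DESeq2 136, of which 46 are shared; limma 62, of which 51 are shared).

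The WSB/EiJ count depended on single mice and on scaling. It was 0 without female cocaine 2, 10 without male cocaine 4, 14 without female sham 3, 24 without male sham 2, 26 without female sham 4, 30 without male cocaine 3 and 114 without male cocaine 2. Scaling to spike-in RNAs, under which the median log2 change of all genes was -0.167, left 0 genes (918 unadjusted). With the cortical score as a covariate the count was 346, and without libraries with a choroid plexus value over 50 it was 6. The cortical marker list had a median of -0.43 and 0 of 12 positive in WSB/EiJ cocaine mice while camera placed it upward (camera adjusted p 0.770, p = 0.817 with an estimated correlation), and the cortical score averaged 3.64 ± 1.06 in cocaine and 3.49 ± 2.03 in sham mice (permutation p 0.873). Medium spiny neuron markers were positive in 15 of 15 (median 0.18, camera adjusted p 0.0870, p = 0.515 with an estimated correlation) and cholinergic markers in 6 of 6 (median 0.26, camera adjusted p 0.199, p = 0.418 with an estimated correlation). With the cortical score as a covariate the camera adjusted p was 0.000353 and 0.00505.

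Among lists in WSB/EiJ, immediate early genes ranked higher with 22 of 24 positive (median 0.36, camera adjusted p 1.35e-10, p = 0.0128 with an estimated correlation). Fosl2 alone passed over all genes and 8 passed adjusted over the list alone, among them Egr2 (1.52 ± 0.43), Nr4a1 (1.19), Egr4 (1.03 ± 0.26), Egr1 (0.78 ± 0.22) and Fosb (0.48 ± 0.19, list-alone adjusted p 0.0359). Heat shock genes ranked higher (median 0.28, 10 of 13 positive, camera adjusted p 5.93e-05, p = 0.00356 with an estimated correlation), with 2 genes past the threshold over all genes and 8 over the list alone, where the cold-inducible RNA-binding gene Cirbp was lower (-0.40 ± 0.11). Circadian genes ranked higher (camera adjusted p 0.00741, p = 0.0445 with an estimated correlation; list alone Per2 0.72 ± 0.21 and Per1 0.43 ± 0.15), as did glucocorticoid-responsive genes (camera adjusted p 0.00741, p = 0.0819 with an estimated correlation; list alone Plin4 0.63). Myelin genes ranked lower with 0 of 17 positive (median -0.12, camera adjusted p 0.00273, p = 0.309 with an estimated correlation; list alone Opalin -0.61 ± 0.17). With an estimated correlation none of these 5 lists passed after adjustment, the lowest adjusted p being 0.0606 for heat shock and 0.145 for immediate early genes.

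A list of 21 endoplasmic reticulum chaperones drawn up after the data were seen had a median of 0.30, 10 members past the threshold over all genes and 14 over the list alone. Because called genes had been seen when it was drawn up, its list tests decide nothing. With it, 6 of 34 lists were called with the preset correlation, 1 (this list) with an estimated correlation and 2 (this list and heat shock genes) by fry. The lists that were not called ran from 0.0870 to 0.994. Signs of median, mean and camera direction differed in 13 of them: GABA interneuron, microglial, endothelial, choroid plexus, ependymal, cortical and dopamine neuron markers, glutamate and GABA-A receptors, endocannabinoid genes, repeated cocaine candidates, interferon genes and genes with known strain variants.

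In C57BL/6J, Col1a1, the type I collagen chain gene of meninges and vessels (chromosome 11, 94936224 to 94953042), was lower after cocaine (-1.81 ± 0.34, edgeR adjusted p 0.0105). It measured 5.43 ± 1.53 CPM in cocaine mice and 20.8 ± 29.0 in sham mice (n 8 each), where 6 sham libraries ran from 4.05 to 8.14, within or near the 3.64 to 7.87 of cocaine mice, and male sham 3 (81.9) and female sham 4 (49.4) stood above them. Leaving out either ended the call (-0.82 ± 0.30, edgeR adjusted p 1.0, and -1.02 ± 0.31, adjusted p 0.758). Outside the naming rule, the nicotinic receptor gene Chrnb4 was called higher (1.98), and Mmp9 (-1.49), Dcdc2c (-1.63) and Gm37199 (-2.01) were lower. Chrnb4 was sparse (mean 0.512 CPM over all libraries), and in C57BL/6J cocaine mice its SD was larger than its mean. Of these mice, 3 of 8 stood above the highest sham value (0.584 CPM) and 8 of 8 above the sham median. The size of its rise is therefore uncertain. The pseudogene Gm13394 (4.27) and the noncoding Gm26825 (2.55) were called only with the 2 libraries nearest to another strain (adjusted p 0.670 and 0.931 without them). With the cortical score as a covariate Gm13394 (adjusted p 0.292), Gm26825 (0.0997) and Gm37199 (0.0997) did not pass. edgeR called 7 genes, 3 higher and 4 lower (817 unadjusted; DESeq2 31, limma 0). The count was 14 without female cocaine 1 or female cocaine 2, 2 without female cocaine 3 and 16 without female cocaine 4. It was 4 without female sham 4, 3 without male cocaine 3 and 0 without male sham 3. Without libraries over a choroid plexus value of 50 it was 0, and with spike-in scaling 1 (median log2 change of all genes 0.154).

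In NOD/ShiLtJ, the photoreceptor and olfactory bulb cadherin gene Cdhr1 (chromosome 14, 37077857 to 37098347) was lower after cocaine (-1.43 ± 0.28, edgeR adjusted p 0.0247), with 6.19 ± 6.38 CPM in sham mice (n 8), the highest sham library reading 20.7. The Cdhr1 call ended without male sham 2 (-0.74 ± 0.26, edgeR adjusted p 0.653), female sham 3 (0.278), female sham 1 (0.168), male cocaine 1 (0.125), male cocaine 2 (0.114), female cocaine 1 (0.0815), male cocaine 4 (0.0779) or female cocaine 4 (0.0610). Of these omissions only that of male sham 2 moved the change far. Without the others it was -1.251 (female sham 3) to -1.445 (female cocaine 4). The predicted zinc finger gene Gm14288, outside the rule, rose by 4.28 ± 0.83 (adjusted p 0.0247, and 0.141 with the cortical score as a covariate). These were the only 2 calls (796 unadjusted; DESeq2 13, limma 2). The count was 0 without female cocaine 1, female sham 3, male cocaine 1 or male cocaine 4, 1 without female cocaine 4, female sham 1, male cocaine 2, male cocaine 3, male sham 1, male sham 3 or male sham 4, 4 without female cocaine 2 or male sham 2, and 7 without female cocaine 3. Without libraries over a choroid plexus value of 50, and with spike-in scaling (median log2 change of all genes -0.129), it was 0.

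In the other 5 strains no gene passed in edgeR. Genes at an unadjusted p under 0.05 numbered 448 in 129S1/SvImJ (0 calls in edgeR, DESeq2 8, limma 0), 6.75% of the tested genes in A/J (0 in edgeR, DESeq2 28, limma 0) and 1114 in CAST/EiJ (0 in edgeR, DESeq2 8, limma 0). They were 918 in NZO/HlLtJ (0 in edgeR, DESeq2 3, limma 0) and 473 in PWK/PhJ (0 in edgeR, DESeq2 8, limma 2). With spike-in scaling the median log2 change of all genes was 0.289 in NZO/HlLtJ (0.171 without male sham 3) and -0.127 in A/J. It was 0.112 in CAST/EiJ and 0.134 in the difference between the sexes. NZO/HlLtJ male sham 3 stood apart, with the largest spike-in share of all libraries (0.902%), the largest share of Gm26917, Gm42418, CT010467.1 and Lars2, which hold rRNA-like sequence (4.23%), the smallest mitochondrial share (1.09%) and the fewest counts (23.2M).

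Whether the response to cocaine differs among strains was tested over all strains at once, and 0 genes passed in edgeR (1064 unadjusted; limma 2; DESeq2 was not run). Among genes the naming rule allows, Hyou1 came nearest (p 0.000138), with a log2 fold change of 0.35 in WSB/EiJ and -0.06 to 0.04 in the others. Nxpe4 followed (p 0.000152; -0.41 in WSB/EiJ, -0.08 to 0.23 elsewhere), then Ppp1r10, a subunit that regulates protein phosphatase 1 (p 0.000162; 0.26 in WSB/EiJ, -0.06 to 0.05 elsewhere), each with an edgeR adjusted p of 0.627.

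Females and males differed most on the sex chromosomes. Genes known to escape X inactivation were higher in females: the translation factor Eif2s3x (chromosome X, 94188707 to 94212862; 140 ± 7.76 CPM in 62 females, 92.7 ± 5.26 in 66 males; log2 0.60 ± 0.01), and the histone demethylases Kdm6a (0.46 ± 0.02) and Kdm5c (0.35 ± 0.02). The noncoding RNAs of the inactivation center stood with them, Xist at 8.24 ± 0.08, Jpx at 0.38 ± 0.03 and Tsix, which overlaps Xist on the opposite strand, at 0.83 ± 0.09. The Y genes Ddx3y (-9.59), Kdm5d (-9.43), Eif2s3y (-9.38) and Uty (-9.29) were lower, but the sex label was itself read from the Y chromosome. Med12, a subunit of the Mediator complex, was the only X gene lower in females (-0.08 ± 0.02, edgeR adjusted p 0.00803). Of the 263 calls, 21 of 657 tested X genes were higher and 1 lower, 6 of 12 Y genes were lower, and 144 autosomal genes were higher and 91 lower.

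On autosomes, Nlrp3, the inflammasome sensor of microglia (chromosome 11, 59541568 to 59566956), was higher in females in 8 of 8 strains (1.39 ± 0.39 and 1.11 ± 0.35 CPM; 0.37 ± 0.06, edgeR adjusted p 8.97e-05). Of 22 protocadherin beta genes tested on chromosome 18, which encode cell-surface molecules that mark single neurons, 7 passed as higher in females and 0 as lower; this family was counted after the values were seen and was not tested as a list. The rule took Pcdhb6 (37333921 to 37337674; 0.25 ± 0.05, adjusted p 0.00248, 8 of 8 strains), Pcdhb8 (37355121 to 37358604; 0.24 ± 0.05, adjusted p 0.00553) and Pcdhb2 (37294812 to 37297624; 0.21 ± 0.05, adjusted p 0.00375). Also higher were the vomeronasal receptor Vmn2r29 (0.38 ± 0.09), the methyltransferase Mettl11b (0.29), the co-chaperone-like Ptges3l (0.27) and the small GTPase Rnd3 (0.23). Lower in females were Acr, the acrosin protease of sperm (chromosome 15, 89568326 to 89574585; -0.35 ± 0.07, adjusted p 0.00114, 8 of 8 strains), and the axon guidance gene Sema3b (-0.26 ± 0.06, adjusted p 0.0115). Sapcd2 (-0.25), the chromatin gene Bend3 (-0.22), the histone gene Hist2h2ab (-0.22), Vsig10l (-0.22), the B-cell cytokine Tnfsf13b (-0.21) and the Myc relative Mycl (-0.20) were lower as well.

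The sex count of 263 genes (165 higher and 98 lower in edgeR, 3177 unadjusted) was 529 in DESeq2 and 226 in limma, 483 with the cortical score as a covariate and 385 (231 higher, 154 lower) without the 2 libraries nearest to another strain. It was 31 without NOD/ShiLtJ, 97 without WSB/EiJ, 113 without CAST/EiJ and 26 with spike-in scaling (20 higher, 6 lower).

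Besides the X escape and Y lists (camera adjusted p 3.47e-129 and 9.57e-171), lists of stress and activity ranked higher in females. Glucocorticoid-responsive genes had 15 of 16 positive (median 0.10, camera adjusted p 2.63e-05, p = 0.0136 with an estimated correlation, fry adjusted p 0.00623), with Pdk4, a switch of fuel use, past the threshold over all genes (0.17 ± 0.04, edgeR adjusted p 0.0329) and 4 genes adjusted over the list alone. Immediate early genes had 20 of 24 positive (median 0.14, camera adjusted p 2.11e-06, p = 0.0564 with an estimated correlation), with the synaptic scaffold Homer1 (0.16 ± 0.04, edgeR adjusted p 0.0116) over all genes and 8 over the list alone. Heat shock genes ranked higher (camera adjusted p 0.0393, p = 0.0973 with an estimated correlation) through Hspa5 (0.20 ± 0.05, edgeR adjusted p 0.0173) and Hsph1 (0.11), while Cirbp was lower (-0.15); without the 2 libraries nearest to another strain this list had a camera adjusted p of 0.0810. With an estimated correlation none of these lists of stress and activity passed after adjustment (adjusted p 0.149 for glucocorticoid-responsive, 0.465 for immediate early and 0.642 for heat shock genes).

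Lists tied to tissue composition were also called for sex at the preset correlation. As marker scores, females minus males gave 0.0761 for medium spiny neurons (permutation p 0.407) and -0.151 for ependymal cells (permutation p 0.0765). Movement of these tissues with sex is therefore not shown. Medium spiny neuron markers were positive in 15 of 15 (median 0.09, camera adjusted p 0.0322, p = 0.449 with an estimated correlation), dopamine genes ranked higher (camera adjusted p 0.0327, p = 0.267 with an estimated correlation; Rgs2, which dampens receptor signaling, 0.24 over the list alone), and mitochondrial transcripts had 12 of 13 positive (camera adjusted p 0.0111, p = 0.279 with an estimated correlation). With the cortical score as a covariate these calls ended (camera adjusted p 0.617, 0.181 and 0.0600). Ependymal markers ranked lower in females (median -0.15, camera adjusted p 0.0190, p = 0.240 with an estimated correlation). Their camera adjusted p was 0.0501 without the 2 libraries nearest to another strain and 0.000363 with the cortical score as a covariate. In all 9 of 33 lists were called, 7 higher and 2 lower, against 2 with an estimated correlation and 3 by fry. The other 24 ran from 0.0943 to 0.923, cortical and myelin markers both at 0.0997. With the cortical score as a covariate, myelin markers (camera adjusted p 0.00919) and repeated cocaine candidates (0.0485) passed as well. Signs of median, mean and camera direction differed for glutamate receptors, choroid plexus, dopamine neuron and blood markers and genes with known strain variants, 5 lists that were not called.

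Whether the difference between the sexes depends on strain was also tested over all strains at once. For Xist, the RNA of X inactivation, the difference was smaller in CAST/EiJ (7.04) and PWK/PhJ (7.68) than elsewhere (8.32 to 8.79; interaction adjusted p 4.65e-06), with male means of 11.9 ± 3.35 CPM in CAST/EiJ (n 10) and 6.61 ± 2.15 in PWK/PhJ (n 8) against 3.73 to 4.71 in the others. edgeR called 2 genes, Xist among them (742 unadjusted), and limma called 9.

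Strain separated more genes than any other factor. Several genes had almost no reads in 1 or 2 strains. The processing notes name only GRCm38, the C57BL/6J genome, and do not say whether strain-specific genomes were used. Cdr1, the locus of the circular RNA that binds the microRNA miR-7 (chromosome X, 61184005 to 61185558), read 0 CPM in all CAST/EiJ and PWK/PhJ libraries and 160 ± 70.7 (C57BL/6J) to 287 ± 69.1 (NOD/ShiLtJ) in the others (n 16 each). Srp54c, a gene of the signal recognition particle family (chromosome 12, 55230168 to 55263836), read 0.151 CPM in CAST/EiJ and 0.201 in PWK/PhJ against 32.4 to 41.0. Ly6c1, a surface protein of brain endothelium (chromosome 15, 75044018 to 75048830), read 0.0258 ± 0.0253 in WSB/EiJ against 10.1 to 18.1. Fam213b, a prostaglandin F synthase gene, read 0.0417 in CAST/EiJ (20.9 in A/J), and the zinc finger gene Zfp605 (chromosome 5, 110110092 to 110129794) 0.0543 in PWK/PhJ. Tpm3-rs7, a tropomyosin-related locus (chromosome 14, 113314608 to 113316754), split the strains otherwise, with 0.229 to 0.261 CPM in 129S1/SvImJ, A/J and C57BL/6J and 29.7 to 41.9 in the other 5.

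The remaining genes with the widest ranges were the vomeronasal receptor Vmn2r85 (0.0131 CPM in CAST/EiJ, 9.30 in A/J), the zinc finger genes Zfp966 (0.0976 in WSB/EiJ, 54.2 in PWK/PhJ) and Zfp973 (0.0558 and 20.3), AK157302 (0.224 in 129S1/SvImJ, 63.2 in PWK/PhJ), Fam205a1 (0.0950 in NZO/HlLtJ, 12.6 in 129S1/SvImJ) and Fam205a4 (1.06 ± 4.20 in A/J, 0.00885 without A/J female sham 1, 16.1 in NOD/ShiLtJ). The test over all strains called 21056 of 21936 genes (edgeR; limma 21044; DESeq2 was not run). The median share of a gene's variance was 43.6% for strain, 0.317% for sex, 0.111% for injection, 2.72% for strain by injection and 42.3% for the residual. Strain by sex had 2.23% and strain by sex by injection 2.52%. Terms with strain have more degrees of freedom than sex or injection, so noise alone gives them larger shares. The 2.72% therefore does not show that the response to cocaine depends on strain.

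Against C57BL/6J, whose genome is the reference, the wild-derived CAST/EiJ and PWK/PhJ differed at 14113 genes (6692 higher, 7421 lower) and 14122 genes (6702 and 7420). In CAST/EiJ, Vmn2r84 was lower (0.00450 CPM against 4.68), and in PWK/PhJ the water channel gene Aqp3 (chromosome 4, 41092722 to 41098183) was higher (5.20 against 0.0185). WSB/EiJ differed at 10033 genes (4890 higher, 5143 lower), with the RNA-editing relative Adad2 higher (9.27 against 0.0494). NZO/HlLtJ, an obese and diabetic strain, differed at 10183 (5028 and 5155); its alpha-globin gene Hba-a2 (chromosome 11, 32296489 to 32297298) read 0.459 CPM against 51.1 ± 21.8, and the actin-like Actbl2 9.09 against 0.0588. NOD/ShiLtJ, a model of autoimmune diabetes, differed at 8083 (4033 and 4050), with Fam205a1 lower (0.135 against 10.2). 129S1/SvImJ differed at 7970 (3809 and 4161) and A/J at 7289 (3479 and 3810). Without the 2 libraries nearest to another strain the counts were 14247 in CAST/EiJ, 14285 in PWK/PhJ, 10015 in WSB/EiJ, 9766 in NZO/HlLtJ, 8909 in NOD/ShiLtJ, 8638 in 129S1/SvImJ and 8242 in A/J.

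The interferon-inducible GTPase gene Gvin1 read 0 CPM in 129S1/SvImJ and 0.598 ± 2.39 in A/J against 8.98 ± 3.08 in C57BL/6J. The meiotic gene Sycp1 read 4.80 and 5.26 against 0.280 ± 1.08. The histone gene Hist1h4m read 29.1 ± 10.7 CPM in C57BL/6J, 2.03 ± 7.99 in A/J and 0.0106 to 0.166 in 129S1/SvImJ, NOD/ShiLtJ, NZO/HlLtJ, PWK/PhJ and WSB/EiJ. Zfp990 read 0.0143 in C57BL/6J and 1.99 (CAST/EiJ) to 3.90 (PWK/PhJ) in 5 of the others, and AK157302 15.5 in A/J against 1.37 ± 4.48. The A/J and C57BL/6J values of these genes include the 2 libraries that lay nearest to the other strain. Without them (n 15 each), A/J read 0.0328 CPM for Hist1h4m, 0 for Gvin1 and 16.5 for AK157302, and C57BL/6J read 31.0, 9.58 and 0.249. Sycp1 read 0.00893 in C57BL/6J, and its log2 difference in 129S1/SvImJ was 8.66 and not 7.06. With spike-in scaling the calls were 3578 higher and 1468 lower in 129S1/SvImJ (median log2 difference of all genes 0.176). In NZO/HlLtJ they were 1140 higher and 5012 lower (median -0.131).

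At the level of transcripts, 1 of 59530 passed for cocaine averaged over strains and sexes, Pqlc1-204 of a lysosomal transporter-like gene (0.85 ± 0.15, mean 5.31 CPM, edgeR adjusted p 0.00935; 2424 unadjusted). The Fosb transcripts, of which 5 of 7 could be tested, had log2 fold changes of 0.09 ± 0.07 (Fosb-201, 9.44 CPM), 0.01 ± 0.10 (Fosb-204, 2.26 CPM), -0.11 ± 0.23 (Fosb-206) and 1.29 ± 0.33 (Fosb-207, 0.366 CPM, p 0.000133, edgeR adjusted p 0.763). Fosb-205, at 0.150 CPM, gave no usable SE.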

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

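In this part, the tests of exchanged labels, of mixed RNA, of WSB/EiJ against the other 7 strains and of regroupings with the cortical score were chosen only after the results were seen. Endoplasmic reticulum and secretory genes such as Hspa5, Hyou1 and Calr rose after cocaine in WSB/EiJ, as did the activity gene Fosl2; in 100 regroupings without the cortical score 5 called as many genes in limma (62, highest other 2086), so chance could not be excluded there. The calls did not hang on the cortical score, since 55 of 55 remained with it as a covariate. There 385 limma calls were the highest of 100 regroupings (highest other 226), but WSB/EiJ had been picked for its calls. The score averaged 3.64 in cocaine and 3.49 in sham mice, while the cortical list had a negative median. The covariate may therefore miss part of a difference in cortical tissue, which is not excluded. A shift among striatal cells is not excluded either, and medium spiny neuron markers were positive in 15 of 15 (camera adjusted p 0.000353 with that covariate). A single library is excluded as the whole cause, since the median change kept at least 84.08% of its size with any library left out, though the count fell to 0 without female cocaine 2. Female cocaine 2 and male cocaine 4, the highest for Hspa5, were not left out together. That these mice carry much of the change is not excluded. Whether other strains share the effect stays open: 55 of 55 genes differed from the mean of the other 7 strains when adjusted over themselves, but they were picked for their change in WSB/EiJ, which voids that test, while over all genes 19 did and the test over all strains called 0 (median 0.271 in WSB/EiJ, 0.000268 in the others in its direction, 29 of 55 with the same sign). The rise may be a response of WSB/EiJ mice to cocaine, a hypothesis found and tested on the same 16 mice, and a new WSB/EiJ cohort would test it.

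The libraries labelled A/J female sham 1 and C57BL/6J female cocaine 3 each lay nearest to the other strain. The 2 libraries point to each other, which is consistent with an exchange of labels or tubes between them (2 of 2 libraries fit). RNA of both strains in the same library is excluded as the whole cause, since the larger distance to the strain they resemble, 0.1296, was within the range of libraries that match their label (up to 0.4985 in NZO/HlLtJ male sham 3 and 0.2385 in the others), though a small share is not excluded and Gabra2 at 106.2 CPM in the library labelled C57BL/6J lay below the other A/J libraries (110.2 to 148). The mouse tag of the library labelled C57BL/6J falls among the numbers of A/J tags, but that of the library labelled A/J lies between A/J and C57BL/6J tags and favours neither. Where the exchange may have happened cannot be told from counts, and breeding and library records would settle it.

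Large decreases against C57BL/6J outnumbered large increases in CAST/EiJ and PWK/PhJ, with 817 genes over 4-fold lower in each and 562 and 583 higher. Reads of divergent strains that match the reference less well could lower counts of genes that are transcribed. The share of decreases was 58.36% in PWK/PhJ and 59.25% in CAST/EiJ, but 62.85% in WSB/EiJ, a strain closer to the reference, so mapping cannot be told from transcription by this test. Absent genes, as Cdr1 may be in CAST/EiJ and PWK/PhJ, would give the same counts, and strain-specific genomes would be needed to separate them.

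Single libraries far from the rest of their group were looked for in total counts, the choroid plexus value and the cortical score; with 6 genes named in WSB/EiJ, for which none was found, 15 were found in 102 tests of groups, where chance flags about 1 in 20 groups (5.1). Each of the 3 measures was tested in 28 groups and each gene in 3. Groups of 3 mice were not tested, so WSB/EiJ female cocaine, which holds female cocaine 2, was not searched. The rate of 1 in 20 assumes normally spread values, and 10 of the 15 were choroid plexus values, which were skewed. Total counts stood apart in A/J male cocaine 2 (90.63M, others 32.5M to 40.6M), C57BL/6J male sham 1 (31.39M, others 41.1M to 43.0M) and WSB/EiJ male cocaine 1 (46.9M, others 32.4M to 35.7M). The choroid plexus value stood apart in 129S1/SvImJ female cocaine 3 (34.03), female sham 5 (763.6) and male cocaine 3 (193), in A/J female cocaine 3 (153.6) and male sham 2 (163.6), in NOD/ShiLtJ female cocaine 3 (137.3), in NZO/HlLtJ female cocaine 2 (266.8), in PWK/PhJ female sham 4 (21.22) and male sham 4 (23.4), and in WSB/EiJ female sham 3 (89.2). The cortical score stood apart in CAST/EiJ male cocaine 3 (2.117, others 5.49 to 5.97) and PWK/PhJ male sham 1 (1.514, others 5.48 to 5.76).

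A difference that depends on both strain and sex drew attention at Xist (edgeR adjusted p 4.646e-06).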

How the results depend on the processing

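Here the tests with spike-in scaling, without the 2 libraries nearest to another strain, without each WSB/EiJ, C57BL/6J or NOD/ShiLtJ library, without NZO/HlLtJ male sham 3 and of WSB/EiJ against the other strains were chosen only after the results were seen. Of the 83 gene results named, none reversed. All 83 kept their side of the threshold with median-of-ratios size factors, the cortical score, the mouse tag, without 7SL and 7SK RNAs and without the 2 libraries (with or without the cortical score). They were 80 with 5 surrogate variables, without the choroid plexus covariate and with the older edgeR test, 75 with limma and with no filter, 70 without libraries over 50, 60 with spike-in scaling, 60 to 78 without a replicate number, and 62 of 62 in DESeq2, whose filter gave no adjusted p to Hspb1, Nxpe4, Plekhg4 and Oard1 in WSB/EiJ. Without a strain, 16 (NOD/ShiLtJ) to 28 of 30 did. Fewer mice or genes, by construction, lower some counts; for the other shifts below the cause was not tested.

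Counts that moved follow, with the main count in parentheses. DESeq2 gave 9 (0) for cocaine on average, 11 (0) in females, 9 (0) in males, 4 (0) for injection by sex and 529 (263) for sex; for cocaine in 129S1/SvImJ 8 (0), A/J 28 (0), C57BL/6J 31 (7), CAST/EiJ 8 (0), NOD/ShiLtJ 13 (2), NZO/HlLtJ 3 (0), PWK/PhJ 8 (0) and WSB/EiJ 136 (55). With 5 surrogate variables sex by strain was 8 (2), cocaine in C57BL/6J 4, PWK/PhJ 1 and WSB/EiJ 191. With no filter sex was 149, cocaine in CAST/EiJ 1 and WSB/EiJ 16. The older edgeR test gave 1 in A/J and 1 in PWK/PhJ, and limma 2 (0) for injection by strain, 9 for sex by strain, 0 in C57BL/6J and 2 in PWK/PhJ. Without libraries over 50 the counts were 2 in A/J, 0 in C57BL/6J, 0 in NOD/ShiLtJ and 6 in WSB/EiJ. The cortical score gave 483 for sex and 346 in WSB/EiJ, the mouse tag 453 for sex. Spike-in scaling gave 26 for sex, 1 for sex by strain, 1 in A/J, 1 in C57BL/6J, 0 in NOD/ShiLtJ and 0 in WSB/EiJ, and against C57BL/6J 5046 (7970) in 129S1/SvImJ, 3111 (7289) in A/J, 9349 (14113) in CAST/EiJ, 3618 (8083) in NOD/ShiLtJ, 6152 (10183) in NZO/HlLtJ, 8931 (14122) in PWK/PhJ and 5101 (10033) in WSB/EiJ. Without NZO/HlLtJ male sham 3 sex had 208, and with spike-in scaling 25. Without the 2 libraries PWK/PhJ had 2, and with the cortical score added sex had 515, C57BL/6J 2, PWK/PhJ 1 and WSB/EiJ 403.

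Leaving out replicate numbers gave 29 to 736 for sex, 0 to 2 for injection by strain, 0 to 1 in females, 2 to 4 for sex by strain, 0 to 1 in A/J, 0 to 11 in C57BL/6J, 0 to 15 in CAST/EiJ, 0 to 2 in NOD/ShiLtJ and 0 to 64 in WSB/EiJ. Sex gave 113 without CAST/EiJ, 31 without NOD/ShiLtJ and 97 without WSB/EiJ. Genes in place of transcripts gave 0 (1). Lists for cocaine (6) were 0 with an estimated correlation, 0 by fry, 11 without the choroid plexus covariate and 11 with the cortical score; lists for sex (9) were 2 and 3 by the former pair, and lists in WSB/EiJ (6) 1, 2 and, with the cortical score, 10. Cocaine in C57BL/6J was 14, 14, 2 and 16 without female cocaine 1 to 4, 4 without female sham 4, 3 without male cocaine 3 and 0 without male sham 3. In NOD/ShiLtJ (2) it was 0 without 4 of the libraries, 1 without 7, 4 without 2 and 7 without female cocaine 3. In WSB/EiJ it was 0 without female cocaine 2, 10 without male cocaine 4, 14 without female sham 3, 24 without male sham 2, 26 without female sham 4, 30 without male cocaine 3 and 114 without male cocaine 2, and 21 genes differed from the mean of the other 7 strains. No paired analysis was possible because the labels pair no mice, and replicate numbers follow accession order only. Depth of at least 23.2M counts left 21936 genes to test; in simulated data, 54% of changes of 1.3-fold within WSB/EiJ were recovered, so smaller effects within a strain could be missed. A p that misses the threshold does not show that values did not differ.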

Other observations

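In this part, the comparisons of receptor, interneuron and immune genes among strains and the regroupings with the cortical score were tests chosen only after the results were seen. Receptors through which drugs of abuse act were among the many genes that differed among strains. Oprm1, the mu opioid receptor (chromosome 10, 6758506 to 7038198), ran from 8.79 ± 2.71 CPM in NOD/ShiLtJ to 20.9 ± 5.05 in NZO/HlLtJ (n 16 each; edgeR adjusted p 1.19e-17), and all 7 opioid genes tested differed, 6 of them with the cortical score as a covariate, as did 19 of 22 dopamine genes, where 21056 of all 21936 genes differed. Drd3, a dopamine receptor, ran from 0.588 ± 0.235 in NOD/ShiLtJ to 2.80 ± 1.77 in CAST/EiJ (adjusted p 7.70e-16), and Drd1 from 160 ± 67.9 in NOD/ShiLtJ to 261 ± 53.6 in NZO/HlLtJ (adjusted p 0.00124, 0.0118 with the cortical score as a covariate; mean cortical scores 4.56 and 3.25), whereas Drd2 did not pass (adjusted p 0.0830). Oprm1 had its lowest and highest means in the same strains as Drd1, so a difference in cortical tissue may enter its range as well. With the cortical score as a covariate 18 of 22 dopamine genes differed. All 12 GABA-A receptor genes differed too, with Gabra2, a subunit tied to alcohol and cocaine behaviour, lowest in C57BL/6J (61.3 ± 14.5) and highest in PWK/PhJ (146), and Gabrg3 running from 51.9 ± 6.00 in PWK/PhJ to 126 ± 17.0 in NZO/HlLtJ.

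Interneuron and immune genes differed too. Npy, the neuropeptide of a class of striatal interneurons, ran from 12.3 ± 3.08 CPM in NZO/HlLtJ to 38.1 ± 4.62 in PWK/PhJ (edgeR adjusted p 2.36e-26), and Slc7a11, the cystine-glutamate exchanger altered by repeated cocaine, from 14.0 ± 2.51 in WSB/EiJ to 62.5 ± 8.56 in NZO/HlLtJ (adjusted p 1.90e-46). Among myelin genes, Mobp ran from 264 ± 61.1 in CAST/EiJ to 991 ± 284 in C57BL/6J and Mog from 20.9 ± 3.51 in WSB/EiJ to 58.7 ± 13.2 in C57BL/6J. The class I histocompatibility gene H2-K1 ran from 1.90 ± 0.342 in CAST/EiJ to 12.3 ± 3.07 in C57BL/6J. It varies in sequence among strains, and its reads may all have been counted against the C57BL/6J genome. The mitochondrial transcript mt-Co2 ran from 52.6 ± 10.9 in A/J to 1659 ± 357 in PWK/PhJ. Its counts may depend on the genome used as well. Poorer matching to the reference would lower counts, however, and the divergent PWK/PhJ was highest. The cause was not tested.

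Regroupings of the mice at random, 100 with the real one included, were counted for every comparison (regroupings with as large a count, real value, highest other; genes at an unadjusted p under 0.05 where limma called 0). For cocaine, chance could not be excluded on average (64; 3.04% and 27.0% of genes), in females (33; 1069; 6783), in males (95; 444; 5121), for injection by sex (46; 897; 6884), for injection by strain (27; 2; 3819), in 129S1/SvImJ (67; 443; 2767), A/J (33; 1123; 6390), C57BL/6J (75; 709; 7693), CAST/EiJ (42; 1165; 7580), NOD/ShiLtJ (9; 2; 13), NZO/HlLtJ (65; 947; 2420), PWK/PhJ (71; 2; 85), WSB/EiJ (5; 62; 2086) or for transcripts (69; 2295; 9957). Nor could it for the number of lists called after cocaine, immediate early genes among them (68; 6; 14), or for the number called for sex (38; 9; 16). The latter does not bear on single lists such as X escape genes (camera adjusted p 3.47e-129). For cocaine the highest regroupings gave more than the real count, which may reflect a structure of the samples. With the cortical score as a covariate, in separate draws, the highest were lower: 11.4% against 27.0% on average and 226 against 2086 in WSB/EiJ. Cortical tissue may thus be part of that structure, and other parts were not tested. With the cortical score as a covariate chance could not be excluded on average (16; 6.37% and 11.4% of genes). In WSB/EiJ the real grouping called the most (1; 385; 226). WSB/EiJ was taken up for its calls and no other strain was regrouped this way, so chance is not excluded there. Chance could be excluded for sex (1; 226; 3), strain (1; 21044; 623) and each strain against C57BL/6J: 129S1/SvImJ (1; 7802; 0), A/J (1; 5852; 3474), CAST/EiJ (1; 13168; 1), NOD/ShiLtJ (1; 8108; 3921), NZO/HlLtJ (1; 9354; 1), PWK/PhJ (1; 12562; 4415) and WSB/EiJ (1; 8842; 2445). The sex count takes in X genes and Y genes, and the sex label was read from the Y chromosome. Autosomal genes were not counted apart in these regroupings, so the exclusion does not bear on them alone. Sex by strain had few regroupings with as many calls (3; 9; 2107). Since 1 of them called 2107 and many comparisons were regrouped, chance is not excluded for that count.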
